A study of Homo sapiens with 4 samples.

How the data were processed

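Protein binding to DNA was measured on a synthetic DNA microarray in 4 samples, each a single array. ETS1 at 100 nM was applied to an untreated array and to an array irradiated with ultraviolet light (UV). c-MYC at 500 nM with its partner MAX at 100 nM was applied to another untreated array and another irradiated array. Bound protein was read as Alexa 635 fluorescence. The UV dose, the scanner software, the scanner gain and the treatment of background are not given in the sources used here.

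Each array held 180880 spots, of which 175866 carried a probe sequence. The probes are synthetic, so no genome build or genomic position applies. A universal set of 120150 spots with 116054 distinct sequences covered most 8-base words many times. A targeted set of 55716 spots with 6945 distinct sequences held designed sites, each on 5 or more spots. Probes were 60 bases long, and those used here shared a common part of 36 bases that contains no adjacent pair of pyrimidines on either strand.

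Per the file headers and the values, the deposited files give spot intensity in arbitrary units, a local median intensity and an adjusted intensity. The authors obtained the adjusted intensity by dividing each unflagged spot by its local median and multiplying by the array median, which corrects for position on the slide and leaves the arrays on their own scales. The other deposited columns hold spot flags and a reference-channel placeholder of constant value, so no correction for the amount of DNA per spot was made. No background column was used, because the files analysed here hold none.

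The adjusted intensity was log2 transformed and the median of the universal probes of the same array was subtracted. This value is called the level, and 0 is the array median. Flagged spots, control spots and spots without a sequence were left out. Universal probes were searched for 8-mers in part of their sequence only. That part was bases 6 to 15 of probes with 1 designed 8-mer and bases 6 to 19 of those with 13 or 14 designed bases. The level of an 8-mer was the median over the universal probes holding it there on either strand. Each 8-mer was joined to its reverse complement, and at least 10 probes were required. This left 32654 8-mers for ETS1 and 32633 for c-MYC/MAX, with a median of 15 probes each. The UV shift was the level on the UV array minus the level on the non-UV array. An 8-mer was counted as higher or lower when its shift was at least 0.5 in size and had the same sign in both of 2 random subsets of its probes. The standard deviation of a shift, estimated from the differences between those subsets, was 0.14 for ETS1 and 0.098 for c-MYC/MAX.

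An enrichment score (E-score) was computed for each 8-mer from the ranks of its probes within a single array. It runs up to 0.5, does not depend on the scale of the scan, and was counted as a call at 0.45 or above. For lists of 8-mers that share a word, the median shift was placed among 10000 random lists of the same size, matched in 20 bins of mean level. These bins are coarse at the top, where strong sites share a bin with much weaker 8-mers. A dipyrimidine step is an adjacent pair of pyrimidines on either strand.

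The lists of words, the seeds, the thresholds and the rule for named 8-mers were fixed before the data were examined. The rule takes, per protein, the 10 8-mers with the highest non-UV E-score, the 5 with the highest UV E-score outside those, and the 8 largest rises and 8 largest falls, skipping 8-mers that share a 6-base word within a set. The seeds were CCGGAAGT for ETS1 and CCACGTGG and ACACGTGT for c-MYC/MAX, each taken with every single-base variant from 4 probes upward. The list for the palindromic CREB site had too few 8-mers with enough probes and is not reported. The comparisons on the targeted probes were added after the probe design was seen. They used the same level, with the mean over the spots of a sequence.

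There was 1 array per protein and condition. No replicate check of any difference between arrays was therefore possible, and no p-values are given. Spreads are over probes, spots or sequences of the same arrays, and the number of arrays limits the precision. The calling steps were tested on simulated data: ETS1 non-UV levels set against themselves, with the measured spot noise (SD 0.142) and seeded changes. All 50 8-mers at each of 4 seeded changes of 1 or 2 log2 units were called. Of the 15145 unchanged 8-mers that were counted, 4 (0.026%) were called. The simulation held 32662 8-mers, and its other unchanged 8-mers are not in this rate. It held no further difference between arrays and no c-MYC/MAX levels. The rate is therefore no estimate of false calls between real arrays.

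Alternatives tried were another size threshold, quantile normalization of the 2 arrays of a protein, division by the median absolute deviation, no centring, residuals from a lowess curve, the unadjusted intensity, means over probes, flagged spots kept, each random subset of probes, 7-mers and 6-mers, other probe minimums and an E-score threshold of 0.40. Probe sets made for other proteins were not used in the comparisons of UV with non-UV binding in the results, and their values are given among the additional observations. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.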

Results

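The data are binding measurements of 2 transcription factors on DNA with and without UV damage. ETS1 is a member of the ETS family, which reads the core GGAA. c-MYC binds DNA with its partner MAX at E-boxes, of which CACGTG is the best known. UV light joins neighbouring pyrimidines of a strand, so DNA sequence sets where lesions can form. The samples fall into 4 groups of 1 array each: ETS1 without UV, ETS1 with UV, c-MYC/MAX without UV and c-MYC/MAX with UV. The labels give 1 array per group, so no value below has a replicate array and spreads are over probes or spots.

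The median intensity of the universal probes was 5504 on the ETS1 non-UV array and 6402 on the ETS1 UV array. It was 4978 on the c-MYC/MAX non-UV array and 15998 on the c-MYC/MAX UV array. On the log2 scale the UV array medians lay 0.22 above the non-UV medians for ETS1 and 1.68 above for c-MYC/MAX. All levels below are relative to the median of their own array, and a shift is the level on the UV array minus the level on the non-UV array. The interquartile range of the universal probes was 0.55 without UV and 0.26 with UV for ETS1, and 0.44 and 0.40 for c-MYC/MAX. Between 287 and 1230 of the 180880 spots per array carried a flag.

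The first comparison asked how UV irradiation of the DNA changed where ETS1 binds. ETS1 signal fell at most of the 8-mers that stood above the array median by 0.5 or more, and of the word lists CGGAAG fell most. The 48 8-mers with CGGAAG, the strong ETS core, had a median level of 2.34 without UV and 0.23 with UV, a shift of -2.10 (SD 0.20 over 8-mers), and all 48 were lower. That shift was -1.04 after quantile normalization, -1.37 with array z-scores, -0.14 against a lowess curve of UV on non-UV level, and -4.36 as a log2 ratio of excess intensity. Their excess above the array median went from 22274 to 1087 intensity units. Of 4423 8-mers at a level of 0.5 or more without UV, 3498 were lower with UV, and 429 8-mers stood at 0.5 or more on the UV array. The 20 8-mers counted as higher were rich in A and T and had levels below the array median without UV.

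In total 3513 of 32654 8-mers (10.8%) were lower and 20 were higher. Scaling changed that split: it was 1198 lower and 142 higher after quantile normalization, 2275 lower and 1 higher with array z-scores, and 2686 lower and 1155 higher without centring. Against the lowess curve, which removes any change shared by 8-mers of equal non-UV level, it was 0 lower and 33 higher.

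**Figure D1:**
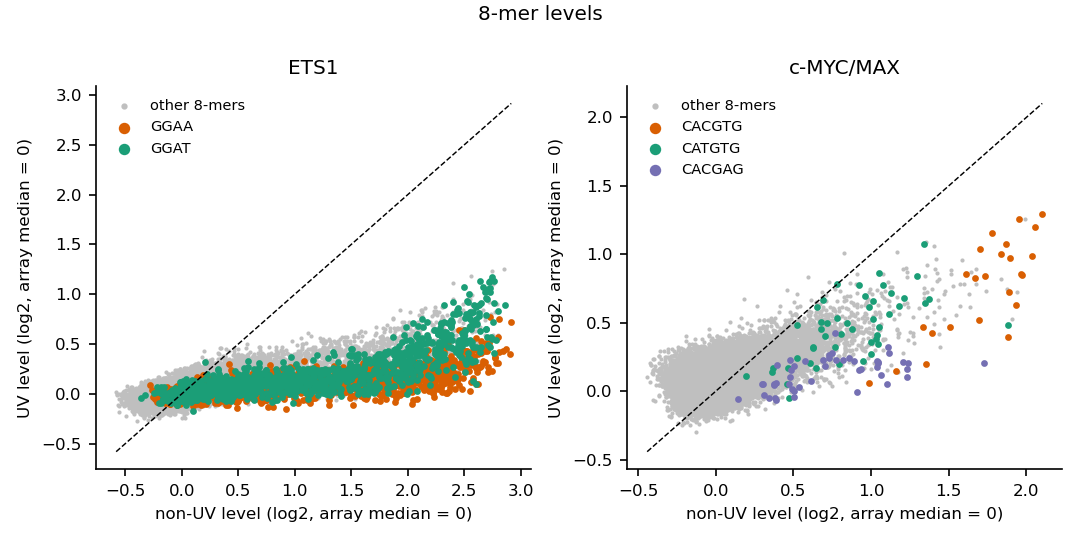
Level of every 8-mer on the UV array against its level on the non-UV array, both log2 with the array median at 0, for ETS1 (left) and c-MYC/MAX (right); the dashed line marks equal levels and colours mark 8-mers with a named word. The slope of UV on non-UV level was 0.19 for ETS1 and 0.35 for c-MYC/MAX, and without centring all c-MYC/MAX points would move up by 1.68.

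Among the ETS1 lists, 8-mers with GGAA outside CGGAAG had a median shift of -0.91 (SD 0.72), and 830 of 1229 were lower. The alternative core CGGAT started at 1.85, had a shift of -1.53 (SD 0.60), and 211 of its 256 8-mers were lower. TTCC is the pyrimidine-rich strand of GGAA, so its list joins the CGGAAG list and that of GGAA outside it. It had a shift of -0.96 with 878 of 1277 8-mers lower. CGGAAG, GGAA outside it, CGGAT and TTCC each lay below all 10000 random lists matched in bins on the mean level of both arrays. The central 95% of those lists ran from -1.74 to -1.48 for CGGAAG, -0.68 to -0.61 for GGAA outside it, -1.35 to -1.20 for CGGAT and -0.73 to -0.66 for TTCC. Each bin holds a range of levels, so these are not comparisons at equal level. After quantile normalization the shifts of GGAA outside CGGAAG, CGGAT and TTCC were -0.46, -0.31 and -0.48. Against the lowess curve they were -0.10, -0.014 and -0.10. The GC-rich word GGGCGG had a level of 0.95 without UV and a shift of -0.58, with 30 of 48 8-mers lower, which turned to 0.24 after quantile normalization and 0.17 against the lowess curve. CCCC had a shift of -0.20, which turned positive under both and without centring. Both lists lay above all matched lists, which ran from -1.08 to -0.80 for GGGCGG and from -0.30 to -0.27 for CCCC, so they fell less than 8-mers in the same bins of mean level.

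The remaining words moved little on the ETS1 arrays. The E-box and E-box-like words CACGTG, CATGTG, CACGCG, CACGAG, CATGCG, CACGTT, CAGCTG and CATATG had shifts of -0.02, 0.02, -0.07, 0.01, -0.03, 0.02, 0.02 and 0.03. The words of other families TGACTCA, ATTGCG and AGGTCA had shifts of 0.04, 0.02 and 0.00, and TCTC had -0.02. A/T-rich words had positive medians: TAATTA had a median shift of 0.29 (SD 0.11, 23 8-mers), TTTT 0.17 (SD 0.34, 1022 8-mers) and CTTT 0.10 (SD 0.37, 1276 8-mers). Against the lowess curve these medians were 0.013, 0.014 and -0.005, but all 3 lay above all random lists matched on mean level, which ran from 0.12 to 0.22, 0.091 to 0.107 and 0.071 to 0.087. Single 8-mers went both ways: TAATTA had 1 counted as higher and 0 as lower, TTTT had 10 and 53, and CTTT had 3 and 90.

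Ranks within each array, which do not depend on scan scale, showed which ETS1 sites kept their place. ETS1 had 794 E-score calls without UV and 475 with UV, of which 314 were shared, so 39.5% of the non-UV calls were kept. At an E-score threshold of 0.40 the counts were 1840, 1346 and 978. Among 8-mers with GGAA and not GGAT, 280 were called without UV and 11 with UV, and 3.93% of the non-UV calls were kept. Among 8-mers with GGAT and not GGAA, 221 were called without UV and 149 with UV, and 57.9% were kept. Among 8-mers with CCGG and neither GGAA nor GGAT, 199 were called without UV and 203 with UV, and 63.3% were kept. Among 8-mers with GGAG and neither of those cores, calls went from 37 to 3. The 161 8-mers called only with UV had a median non-UV E-score of 0.434.

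Single 8-mers showed the same order. The 8-mer of highest non-UV E-score, CCGGAAGC, went from a level of 2.92 to 0.73 and from an E-score of 0.496 to 0.468. CCGGCGGA, another of the top set, went from 2.85 to 1.26 and kept an E-score of 0.492. The highest UV E-scores outside the non-UV top set were those of GGACCGGA at 0.493, GGGCAGGA at 0.492, ATCCGGCC at 0.492, ACTACCGG at 0.491 and ACATCCGC at 0.489, with UV levels from 0.84 to 1.23. The largest falls were in ATTTCCTC, which fell by 2.52 to a UV level of 0.03, and CCGGAAAG, which fell by 2.52 to 0.23. Of the 8 named largest falls, which ranged from -2.52 to -2.26, 6 held GGAA. The largest rise was 0.59 in ATAAAAAA, from -0.58 to 0.01, and the 8 named rises ended at UV levels between -0.01 and 0.08. Negative control spots on the ETS1 non-UV array read 4676 units against 5418 at universal spots, so these rises started near or below the controls.

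Substitutions in the seed CCGGAAGT, with positions counted from 1 at its 5′ end, separated binding from its loss after UV. The seed had a level of 2.81 without UV and 0.75 with UV. A6T had 2.76 and 1.13, A6C had 2.75 and 1.10, and A5T had 2.67 and 0.84, which made them the 3 of 24 variants above the seed on the UV array. A6G had 2.70 without UV and 0.50 with UV, and C1T had 2.42 and 0.05. Every substitution at G3 or G4 brought the level without UV down to between 0.03 and 0.53.

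The targeted probes tested the same sites in designed sequence, with 110 spots for each template. The template CGTGTATACCGGATGCATGCGTAT with a CCGGAT core had a mean level of 2.73 ± 0.15 (SD over spots) without UV and 0.88 ± 0.14 with UV. The template CGTGTATACCGGAAGCATGCGTAT with a CCGGAA core had a UV level of 0.32 ± 0.21 and a shift of -2.18. In the other sequence context, CCGGAT had 2.79 ± 0.17 and 1.07 ± 0.21, and CCGGAA had 2.59 ± 0.15 and 0.43 ± 0.31. Changes that reached the base directly 5′ of the CCGGA core and added 2 dipyrimidine steps hardly changed the level without UV (mean -0.04, SD 0.16, 40 sequences) and changed it by -0.25 (SD 0.20) with UV. In 31 of those 40 sequences the shift was lower than in the template. In 8 sequences with changes there that added no dipyrimidine the changes were -0.03 without UV and 0.05 with UV. At the other positions 2 added steps did not lower the shift in this way. The shift changed by 0.05 (lower in 13 of 40) for changes 2 bases away on the 5′ side, by 0.00 (23 of 48) further away on that side, and by -0.02 (86 of 168) 3 or more bases away on the 3′ side. Changes 2 bases away on the 3′ side and in the core cost binding without UV, with mean changes of -0.83 and -1.43, and their shifts changed by 0.12 (lower in 9 of 24) and 0.74 (lower in 0 of 24).

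**Figure D2:**
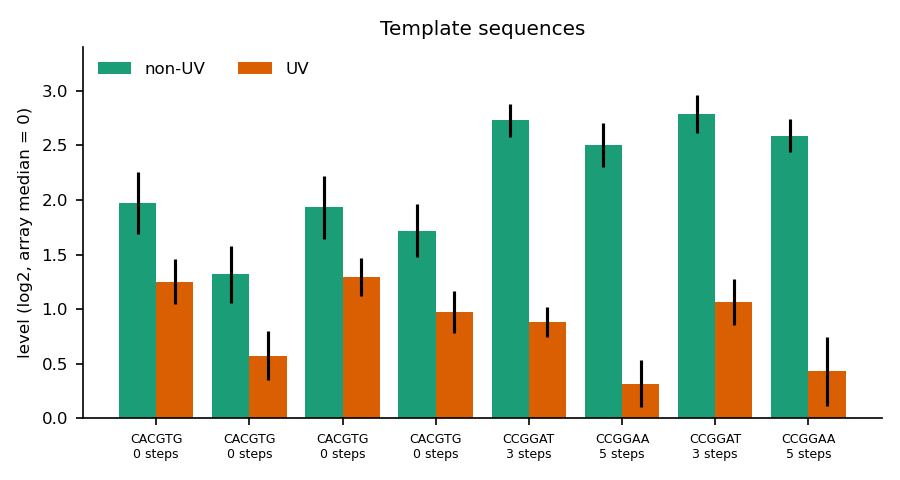
Mean level over about 110 spots of each of the 8 template sequences on the non-UV and UV arrays (log2, array median at 0; bars with SD over spots), labelled with core and number of dipyrimidine steps; CACGTG templates are from the c-MYC/MAX arrays and CCGGA templates from the ETS1 arrays. UV levels were 0.88 and 1.07 for CCGGAT and 0.32 and 0.43 for CCGGAA, while CACGTG templates shifted by -0.64 to -0.75, a direction that turns without centring.

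Among 1382 targeted ETS1 site sequences the median shift was -1.83 (SD 0.38), and 1375 were lower by at least 0.5. With array z-scores the median was -1.09, and the mean shifts of the templates were -1.33 for CCGGAA and -0.58 for CCGGAT. The shift grew with the number of dipyrimidine steps in the probe. It was -1.42 in 48 sequences with 2 steps, -1.56 in 198 with 3, -1.72 in 342 with 4, -1.97 in 398 with 5, -2.03 in 312 with 6 and -2.24 in 82 with 7. The same order held among sequences of similar non-UV level (within 0.25 of 2.5), from -1.50 with 2 steps to -2.39 with 7. Core and number of steps are not separated in these values. At that non-UV level 33 sequences with GGAA and 116 with GGAT had 4 steps, against 152 and 41 with 5 steps. From 4 to 5 steps the median UV level went from 0.39 to 0.34 with GGAA and from 0.83 to 0.48 with GGAT. Designed sites with a CCGGAA core had mean levels of 2.27 without UV and 0.29 with UV over 6 sequences. Those with CCGGAT had 2.12 and 0.53 over 6 sequences, and those with CCGGTA 1.80 and 0.48 over 10 sequences.

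The second comparison asked the same of c-MYC/MAX. CACGTG had the highest median level of the word lists on both arrays but stood less far above the array median with UV. All 24 8-mers with CACGTG were lower relative to the array median, with a median level of 1.81 without UV and 0.85 with UV, a shift of -0.92 (SD 0.21). The matched random lists ran from -0.34 to -0.16, and the shift was -0.65 after quantile normalization and -0.006 against the lowess curve. In absolute intensity the same 8-mers rose: without centring the median shift was 0.76, and their excess above the array median was 12450 units without UV and 12754 with UV. Dark-corner spots rose too, from 1750 to 6931 units, and the scanner gain is not given. The rise in units is therefore no measure of bound protein. E-boxes without dipyrimidines kept more signal than those with them.

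In total 240 of 32633 8-mers were lower and 67 were higher. The split was 95 lower and 73 higher after quantile normalization, 200 and 69 with array z-scores, and 177 and 209 when arrays were centred on probes without dipyrimidines. Without centring it was 0 lower and 32620 higher, and against a lowess curve 1 lower and 3 higher. With the unadjusted intensity it was 896 lower and 952 higher.

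The other E-box-like words also stood lower relative to the array median, and each of these shifts turned positive without centring. CACGAG had a shift of -0.51 (SD 0.29) with 25 of 48 8-mers lower, CACGCG -0.49 (SD 0.19) with 21 of 48, and CATGTG -0.38 (SD 0.25) with 15 of 48. CACGTT had -0.33 with 2 of 48 lower and CATGCG -0.27 with 8 of 48. The first 4 lay below all matched lists, whose bins are coarse at this level, while CATGCG lay within their central 95% of -0.27 to -0.15. Against the lowess curve CATGTG, CACGCG and CATGCG turned to 0.018, 0.040 and 0.052, while CACGAG and CACGTT did not turn. In intensity units the excess above the array median fell only for CACGAG of these 5, from 3196 to 1880, and rose from 4071 to 6240 for CATGTG, 5518 to 7444 for CACGCG, 3300 to 5773 for CATGCG and 2232 to 2560 for CACGTT. CATATG, an E-box of other helix-loop-helix proteins, had -0.12, and TGACTCA had -0.11. The E-box CAGCTG had -0.02, GGGCGG -0.04, AGGTCA -0.01, ATTGCG 0.07 and CGGAT 0.04. The words CCCC and TCTC had shifts of 0.02 each. TTTT was higher by 0.26 (SD 0.14, 1020 8-mers), TAATTA by 0.25 (SD 0.08, 23 8-mers) and CTTT by 0.19, and 46 of the 67 8-mers counted as higher held TTTT. Against the lowess curve the medians were 0.079, 0.047 and 0.045. GGAA outside CGGAAG, TTCC and CGGAAG each had 0.11.

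By rank, c-MYC/MAX had 198 E-score calls without UV and 105 with UV, and 66 were shared, so 33.3% of the non-UV calls were kept. These 3 counts depended on the settings: they were 903, 609 and 410 at a threshold of 0.40, 431, 311 and 164 in random subset 1 of the probes and 378, 325 and 154 in subset 2, and the unadjusted intensity gave 69 UV calls and 39 shared. Of the 8-mers with CACGTG, 23 were called without UV and 14 with UV. CACGAG went from 12 calls to 0, CATGTG from 17 to 7, CACGCG from 24 to 9 and CATGCG from 10 to 7. The share kept was 76.9% among called 8-mers with 0 dipyrimidine steps, 39.2% with 1, 16.9% with 2, 20.8% with 3, and 0 of 10 calls were kept with 4 or more. Starting level was not held equal: the median non-UV level of these called 8-mers was 1.36, 1.21, 1.11, 1.06 and 1.10 in that order. It was 1.78, 1.86 and 1.79 among called CACGTG 8-mers with 0, 1 and 2 steps. Within CACGTG, 7 of 7 called 8-mers without dipyrimidines were kept, 7 of 12 with 1 step and 0 of 4 with 2 steps. Their UV levels were 1.08, 0.85 and 0.46 in that order.

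The 8-mer GCACGTGC, with no dipyrimidine, had the highest non-UV E-score that the rule named and went from a level of 2.06 to 1.20. The seed ACACGTGT, also without dipyrimidines, went from 2.10 to 1.29 over 12 probes, with shifts of -0.03 and -0.89 in the 2 random subsets of them. The seed CCACGTGG, with 2 dipyrimidine steps and 8 probes, went from 2.93 to 0.83. Positions in the seeds are counted from 1 at the 5′ end. In CCACGTGG, C1A left 2.04 without UV and 0.99 with UV, above the seed on the UV array, while A3T had 1.73 and 0.21. In ACACGTGT, A1G had 1.70 and 1.04, C4T had 0.92 and 0.77, and A3T had 0.70 and 0.18. Relative to the array median, CCACGAGG fell by 1.52 and CCACGTGA fell by 1.49. Among 8-mers of high UV E-score, ACATGTGC had levels of 1.34 and 1.08, GTGACGCA 1.17 and 1.01, and GCCGCACA 0.91 and 0.72, none of them counted as lower. The largest rises were in AAGATAAA at 0.65, ATTTGAAA at 0.63 and TTAAAAAA at 0.63, and all 67 8-mers counted as higher were below the array median without UV.

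The 4 CACGTG templates hold no dipyrimidine at all, and they were lower relative to the array median as well. Their mean levels without UV were 1.97 ± 0.29, 1.32 ± 0.26, 1.93 ± 0.29 and 1.72 ± 0.24, and their shifts were -0.72, -0.75, -0.64 and -0.75. Without centring their mean shift turned to 0.97. Changes that reached the base next to CACGTG and added 2 dipyrimidine steps changed the shift by -0.16 (SD 0.28), and the shift was lower than in the template in 59 of 80 sequences. Changes there that added no dipyrimidine changed it by 0.25 (SD 0.16) over 16 sequences. Both kinds also cost binding without UV, with mean changes of -0.43 (SD 0.43) and -0.36 (SD 0.33). Changes that added 2 steps moved it by -0.09 (SD 0.19, lower in 56 of 80) 2 bases away and by -0.04 (SD 0.15, lower in 156 of 256) 3 or more bases away.

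Among 482 targeted c-MYC/MAX site sequences the median shift was -0.70 (SD 0.38), which was 0.98 without centring. It was -0.39 in 68 sequences without dipyrimidines, -0.51 in 160 with 1 step, -0.81 in 174 with 2, -1.04 in 58 with 3, -1.18 in 16 with 4 and -1.20 in 6 with 5. Among sequences within 0.25 of a non-UV level of 1.5 it ran from -0.47 without dipyrimidines to -1.36 with 4 steps, the last over 7 sequences. Sequences with CACGTG had -0.63 (SD 0.21, 28 sequences) without dipyrimidines and -1.22 (SD 0.39, 22 sequences) with 3 or more steps. Differences between sequences on the same pair of arrays do not depend on centring.

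**Figure D3:**
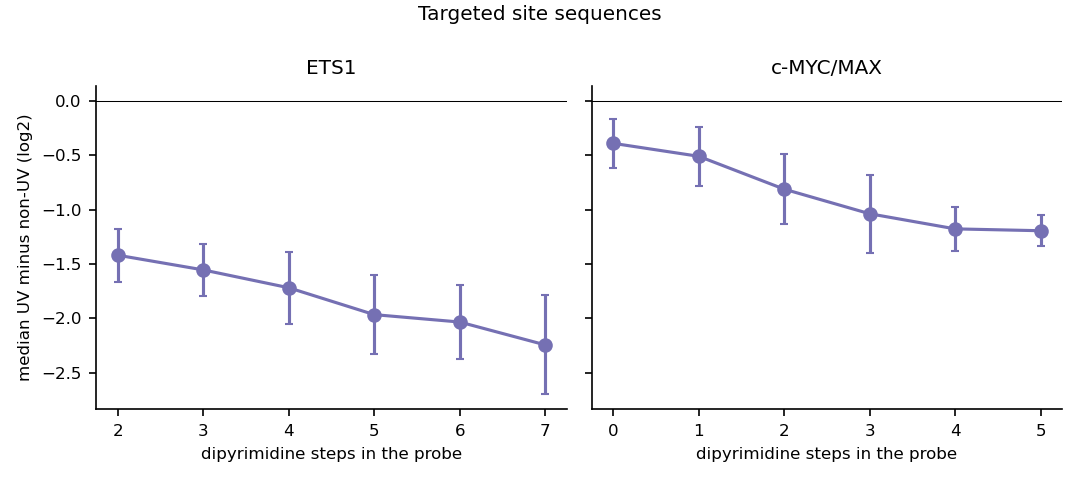
Median shift of targeted site sequences (UV minus non-UV, log2; bars are SD over sequences) by number of dipyrimidine steps in the probe, for ETS1 (left) and c-MYC/MAX (right). The shift went from -1.42 at 2 steps to -2.24 at 7 for ETS1 and from -0.39 at 0 steps to -1.20 at 5 for c-MYC/MAX, and without centring all c-MYC/MAX points would move up by 1.68. The mix of GGAA and GGAT cores among the ETS1 sequences also changed with the number of steps.

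The third comparison asked whether dipyrimidines alone set the shift, over all universal probes. For ETS1 the median shift was 0.03 in probes without dipyrimidines and -0.29 in probes with 10 steps. The difference between probes with 10 or more steps and those with 0 or 1 was -0.32, and it was -0.11 after quantile normalization, -0.17 with array z-scores and -0.001 against the lowess curve. Among probes that hold neither GGAA nor GGAT it was 0.02 with 0 or 1 step and 0.00 with 10 or more. For c-MYC/MAX it went the other way, from -0.11 without dipyrimidines to 0.15 with 10 steps, and among probes without its words from -0.09 to 0.17. By kind of step, TT went with a rise in both proteins: probes without TT had -0.12 for ETS1 and -0.13 for c-MYC/MAX, and probes with 5 TT steps had 0.24 and 0.36. CC went with a fall for ETS1, from 0.12 without CC to -0.45 with 5 CC steps, and with little change for c-MYC/MAX, 0.00 and -0.01. These ETS1 probes differed in level before UV, from -0.22 without CC to 0.82 with 5 CC steps and from 0.10 without TT to -0.27 with 5 TT steps. So did the c-MYC/MAX probes, from -0.12 to 0.28 by CC and from 0.071 to -0.19 by TT. TC went from 0.04 to -0.18 with 4 steps for ETS1 and from -0.02 to 0.01 for c-MYC/MAX. CT went from -0.07 to 0.03 with 4 steps for ETS1 and from -0.05 to 0.05 for c-MYC/MAX.

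By the number of steps within the 8-mer, the ETS1 shifts from 0 to 5 steps lay between -0.01 and 0.01. With 6 steps the shift was -0.11, which turned to 0.10 without centring, and with 7 steps it was -0.33. The 8-mers that are all pyrimidine on 1 strand are those with 7 steps. For c-MYC/MAX the shifts from 0 to 7 steps were -0.11, -0.07, -0.02, 0.03, 0.06, 0.11, 0.13 and 0.16.

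The last comparison asked whether the same 8-mers shifted for both proteins. Across 32620 8-mers, which are not replicates, Pearson's r of the 2 shifts was 0.112 and Spearman's rho was 0.335. Among 27057 8-mers below 0.5 on both non-UV arrays, and so outside the strong sites of either protein, r was 0.410 and rho 0.418. There were 10 8-mers lower for both proteins, against 25.8 if the lists were independent, and 4 higher for both, against 0.041.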

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

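The tests on the dark corners, the intensity range, the templates and the GGAT and GGAA sites were chosen after the results were seen, except those on the detector's ceiling and on the mean over equal numbers of steps.

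Some groups of 8-mers had shifts of opposite sign for ETS1 and c-MYC/MAX, and with 1 array per group the difference between the proteins was not tested. CGGAAG had -2.10 for ETS1 and 0.11 for c-MYC/MAX. GGAA outside CGGAAG had -0.91 and 0.11, and TTCC, whose list joins both of these, had -0.96 and 0.11. The 8-mers with 6 dipyrimidine steps had -0.11 and 0.13, and those with 7 steps had -0.33 and 0.16. Probes with 10 or more dipyrimidine steps differed from those with 0 or 1 by -0.32 for ETS1 and by 0.30 for c-MYC/MAX. The ETS1 difference was -0.001 against the lowess curve, and among probes without GGAA and GGAT the shift was 0.02 with few steps and 0.00 with many, while c-MYC/MAX probes without its words went from -0.09 to 0.17. Without centring the ETS1 value for 6 steps turned to 0.10, the sign it has for c-MYC/MAX.

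CACGTG stood lower relative to the array median on the c-MYC/MAX UV array, on an array whose intensity was higher throughout. A signal added equally to every spot is argued against, because the shift was -1.04 (SD 0.29 over 8-mers) once the dark-corner intensity of each array was subtracted. At equal scanner gain, 1 added equally to DNA spots alone is argued against because intensity differences among other 8-mers grew (interquartile range 2.25 times as wide). The gain is not given, and a higher gain on the UV array would widen these differences too. It would widen the excess of CACGTG above the array median as much, yet that excess went from 12450 to 12754 units. The detector's ceiling is argued against too, since 5.39% of 1094 universal spots with CACGTG were at the highest value. Dipyrimidines in the probe are argued against as the whole cause of this relative fall by the templates that hold none, with a mean shift of -0.71 (SD 0.05 over 4 templates), but that mean is 0.97 without centring, other sites without dipyrimidines fell less (median -0.39 over 68 sequences, and -0.11 in a designed CACGTG sequence), and the loss was larger in sites with more of them. An added signal that differs between spots stays open, and values that go with it are the excess of CACGTG above the array median (12450 and 12754 units) and a rise of 5181 units at dark corners against 10963 at universal spots; more unspecific binding on irradiated DNA and competition of lesions for the protein stay open as well and were not tested.

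ETS1 sites with GGAT kept more signal after UV than sites with GGAA. A higher starting level of GGAT sites is argued against by the difference of 0.49 in UV level among site probes of similar non-UV level, and a narrower range of the UV array by the difference of 54.0 percentage points in rank-based calls kept. The number of dipyrimidine steps gave a mixed picture: at equal level and equal steps GGAT stood 0.29 above GGAA on average, 0.43 above with 4 steps (SE 0.04) and 0.14 above with 5 steps (SE 0.06). The number of steps is therefore argued against as the whole cause at 4 steps and left open at 5. For base changes 5′ of the core the shift differed by place. In the templates, changes that reached the base directly 5′ of CCGGA and added 2 steps changed the shift by -0.21. The SD was 0.25, and the shift was lower in 31 of 40 sequences. An added step there can pair that base with the C that opens the core. Changes 2 bases away on that side that added 2 steps changed the shift by 0.05 (SD 0.12, lower in 13 of 40). Whether the place of the dipyrimidines within the core matters stays open, because changes in the core of the templates also cost binding without UV.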

How the results depend on the processing

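The settings that centre on probes without dipyrimidines, use all probes with the common part, take ratios of the excess over the array median or subtract dark corners, and all settings on the targeted probes, were chosen after seeing the data. Of 1448 recomputed values, 1025 stayed within the spread or within 1.5 times a count, 364 moved beyond that, and 59 changed the sign of a value counted as changed. Those 59 came from quantile normalization, no centring, the lowess residual or the ratio of excess intensity. Values not counted as changed turned sign 104 times, under 12 settings, and stand among the first 2 counts. Among values for single words and 8-mers, 933 stayed within the spread, 194 moved to a smaller size, 82 moved to a size as large or larger, and 55 counted as changed turned sign. A spread can exceed the value itself, so staying within it does not mean that the size held. For ETS1, TTTT at 0.014 against the lowess curve (main value 0.165) and CCCC at -0.015 with array z-scores (main value -0.203) count as within it. No paired analysis was possible because each group held a single array. The setting that leaves out 5 bases at each end of the probe was not run, since the designed part is then shorter than an 8-mer. Signal over background limits the weak end: the c-MYC/MAX UV array stood higher at universal, negative control and dark-corner spots. On the ETS1 non-UV array the negative control spots read 4676 units against 5418 at universal spots. The cause of a change was not tested for any value below unless it is stated.

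Quantile normalization gave 1198 lower and 142 higher 8-mers for ETS1 and 95 lower for c-MYC/MAX. The shift of CGGAAG was -1.04, that of CACGTG -0.65, and the difference between ETS1 probes of many and few dipyrimidines -0.11. The ETS1 lists GGGCGG and CCCC turned to 0.24 and 0.059, and single 8-mers turned as GGACCGGA 0.10, GGGCAGGA 0.42, ATCCGGCC 0.061 and ACATCCGC 0.17.

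With array z-scores ETS1 had 2275 lower and 1 higher 8-mers. CGGAAG had a shift of -1.37, the CCGGAA templates -1.33, the CCGGAT templates -0.58 and the ETS1 site probes -1.09. The ETS1 difference by dipyrimidines was -0.17.

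Without centring the changes of sign follow from the array medians, since 0.22 is added to every ETS1 shift and 1.68 to every c-MYC/MAX shift. ETS1 had 1155 higher 8-mers, CGGAAG had -1.88, CCCC 0.015 and 8-mers with 6 dipyrimidine steps 0.10. For c-MYC/MAX 32620 8-mers were higher and 0 lower. The lists turned as CACGTG 0.76, CATGTG 1.30, CACGCG 1.19, CACGAG 1.18, CATGCG 1.41, CACGTT 1.35, CATATG 1.56, TGACTCA 1.58 and 0 dipyrimidine steps 1.58. The CACGTG templates had 0.97 and the site probes 0.98. Single 8-mers turned as GCACGTGC 0.83, CCACGCGG 0.47, ACGTGGGC 0.30, ACGTGTCC 0.67, CCACATGG 0.29, CCACGAGG 0.17, CCATGCGG 0.77, CGGCCACG 1.04, ACGTGCCC 0.95, ACACGTGT 0.87, CCACGTGA 0.20, CCATGAGG 0.65 and AAGCACGT 0.79.

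The lowess residual removes by construction what 8-mers of equal level share. It left 0 lower and 33 higher 8-mers for ETS1, 1 lower and 3 higher for c-MYC/MAX, -0.14 for CGGAAG, -0.006 for CACGTG and -0.001 for the ETS1 difference by dipyrimidines. The agreement between proteins was 0.205 (Pearson) and 0.242 (Spearman). ETS1 lists turned as GGGCGG 0.17, CCCC 0.068 and CTTT -0.005, and c-MYC/MAX lists as CATGTG 0.018, CACGCG 0.040, CATGCG 0.052 and 0 dipyrimidine steps 0.033. Single 8-mers turned as CCGGAAGC 0.25, CCGGCGGA 0.79, CCGGACGG 0.44, CCGGATAC 0.42, TCCCCGGA 0.14, GAGCCGGA 0.081, GGACATCC 0.46, CCACTTCC 0.017, ACCTCCGG 0.059, GGACCGGA 0.78, GGGCAGGA 0.72, ATCCGGCC 0.68, ACTACCGG 0.41, ACATCCGC 0.58 and ATCCCCGG 0.025 for ETS1, and as GCACGTGC 0.26, ACGTGCCC 0.34, ACACGTGT 0.33 and AAGCACGT 0.002 for c-MYC/MAX.

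The unadjusted intensity gave 316 higher 8-mers for ETS1 and 952 higher and 896 lower for c-MYC/MAX, with 69 UV calls and 39 shared. The ETS1 difference by dipyrimidines was -0.42, and the agreement was 0.169 and 0.299. Means over probes gave 13 higher 8-mers for ETS1 and 18 for c-MYC/MAX. Centring on probes without dipyrimidines gave 5 and 209. The log2 ratio of intensity above the array median was -4.36 for CGGAAG and 0.035 for CACGTG, and CGGAAG had -3.11 after subtraction of dark corners.

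A size threshold of 1 left 0 higher and 2055 lower 8-mers for ETS1 and 0 and 25 for c-MYC/MAX. At least 20 probes, which tests fewer 8-mers, left 2 and 939 for ETS1 and 4 and 97 for c-MYC/MAX. Single random subsets of probes, each with fewer probes, gave 81 and 80 higher 8-mers for ETS1 and 149 and 148 for c-MYC/MAX. In the first subset c-MYC/MAX had 431 calls without UV, 311 with UV and 164 shared, and in the other 378, 325 and 154. An E-score threshold of 0.40 gave 1840, 1346 and 978 for ETS1 and 903, 609 and 410 for c-MYC/MAX.

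With 7-mers, fewer in number, ETS1 had 0 higher, 735 lower, 143 calls without UV, 80 with UV and 54 shared. c-MYC/MAX had 2, 33, 29, 6 and 6 in that order, and the agreement was 0.130 and 0.449. With 6-mers, fewer in number, ETS1 had 0 higher, 152 lower, 24 calls without UV, 13 with UV and 8 shared. c-MYC/MAX had 0, 6, 4, 1 and 1 in that order, and the agreement was 0.152 and 0.528.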

Other observations

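The tests on TTTT below were written before their results were seen, except the one on ranks, which was chosen afterwards, and the values on other probe sets were looked at only after the probe design was known. The rank test took the place of one set in advance for c-MYC/MAX, division of each array by its median absolute deviation, which decides nothing there because those deviations were 0.21 and 0.20 and the shift of TTTT only went from 0.26 to 0.27.

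Some double sites started high and shifted like single ones. Probes with 2 CCGGT sites, GTATGCACCGGTACCGGTACGCGC and GTATGCGTACCGGTACCGGTGCGC, had mean levels of 3.10 and 3.26 without UV and 1.76 and 1.92 with UV over 10 spots each. Their shifts were -1.33 and -1.34, against a mean of -1.32 for single CCGGTA sites, which had 1.80 and 0.48. The other 4 designed double probes, which lack CCGGT, were low already without UV. Their levels ran from 0.12 to 0.66 without UV and from 0.12 to 0.33 with UV, with shifts from -0.33 to 0.01. For c-MYC/MAX, the designed E-box sequences differed in their shift although none holds a dipyrimidine: GTATGCGCACGTGCGTATGTATGC had -0.70 and GTATGCACACGTGTGTATGTATGC had -0.71, while GTATGCACACGTGCGTATGTATGC had -0.11, from 1.39 to 1.28.

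Probes designed for EGR1, a zinc finger protein, also carried c-MYC/MAX signal. Their median level over 196 sequences was 0.68 without UV and 0.25 with UV, and 41 were lower by at least 0.5. Those with CACGC, which overlaps the E-box-like word CACGCG, had 0.83 without UV over 130 sequences, and those without CACG had 0.10 over 53 sequences. Probes designed for GATA, E2F1, RUNX and CREB1 had median shifts between -0.18 and -0.05 for c-MYC/MAX and between -0.15 and 0.04 for ETS1.

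Control spots moved apart between the proteins. On the c-MYC/MAX arrays the negative control spots rose from 2297 to 6081 units and the dark-corner spots from 1750 to 6931. On the ETS1 arrays they went from 4676 to 3949 and from 3458 to 3266.

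TTTT 8-mers stood higher on both UV arrays, from levels below the array median. On the ETS1 non-UV array the negative control spots read 4676 units against 5418 at universal spots. The ETS1 rise of TTTT therefore started near the intensity of these controls. A narrower range of the UV array keeps the order of 8-mers apart from noise and is argued against for c-MYC/MAX, where the median percentile of TTTT among all 8-mers went from 12.9 to 64.1, past the middle, while for ETS1 it stays open, since the percentile went from 16.8 to 39.7 and the shift of 0.11 with each array divided by its median absolute deviation lay too near the bound set in advance. How far 8-mers of equal level share the change stays open, since against the lowess curve of UV on non-UV level the shift was 0.079 for c-MYC/MAX and 0.014 for ETS1, while random lists matched on the mean level of both arrays had only 0.069 to 0.090 and 0.091 to 0.107 against the measured 0.26 and 0.17. At equal number of A and T, 8-mers with 2 or more TT steps stood 0.18 above those with none for c-MYC/MAX (range 0.15 to 0.22 over A and T numbers from 3 to 7), and for ETS1 the difference was 0.066 (range 0.00 to 0.15), which leaves the question open. Sites of TT lesions may draw some c-MYC/MAX signal after UV, as a hypothesis only, since that comparison was not matched on level and no array without protein was analysed here.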
